A study of Mus musculus with 8 samples.

How the data were processed

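RNA was measured in 8 mouse samples: SRSF3 knockout hearts (3), control hearts (3) and SRSF3-GFP iCLIP of neonatal cardiomyocytes (2 replicates). Per the labels' protocols, knockout and control mice received 3 injections of 1 mg 4-hydroxytamoxifen and hearts were taken 5 days after the last. For iCLIP, per the labels' protocols, cells of newborn C57BL/6 pups were plated, transfected with 15 µg of modified mRNA and 21 µL of Lipofectamine 2000, and irradiated 48 h later with 100 mJ of UV light at 254 nm. RNA was cut to 80 to 200 nt with RNase I, precipitated through the GFP tag with a goat antibody, ligated to an adapter, reverse-transcribed with barcoded primers, circularised and amplified. Samples were grouped by the labels. The 6 heart samples are not analysed here.

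The authors' deposited iCLIP tracks hold a signed score for each single nucleotide position, whose size is the number of cDNAs and whose sign is the strand, per the file headers and the values. The scores are not scaled to library size. Per the file headers they are cDNA hits on the mm9 genome with annotation Ensembl 59, and per the submitters' processing notes reads were mapped with Bowtie 0.10.1. How duplicate cDNAs were collapsed, how reads with several matches were handled and whether positions were filtered is not given in the sources used here. Both replicates carry the same library identifier in their headers, and the merged track is the sum over 5 libraries, of which 3 carry other identifiers. The merged track was described in the report. Its excess over the 2 replicates, 1138453 cDNAs, is called the other libraries in the closing section, where it was compared with the replicates.

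Depth was 815414 cDNAs in replicate 1 and 2253688 in replicate 2. cDNAs per window or gene were divided by the library total and given per 1000000 cDNAs (CPM). Means and SDs are over the 2 replicates. Intervals are 95% Wilson intervals for shares and exact 95% Poisson intervals for counts, the limit of a 0 is 3 cDNAs, and these, like the exact binomial p-values, cover counting error only. Coordinates are 1-based and in mm9.

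The reference used here was GENCODE M21 on GRCm38, another build, and no coordinate was converted. Nuclear windows are therefore named by position and not by gene, and binding per gene region and binding of the 18 gene lists fixed for cardiac, splicing and cell type genes were not computed. Mitochondrial genes were the exception. The plan was to name them where the chromosome had the same length in both builds, but no length of the mm9 sequence was used here, so the numbering was tested on the data instead. The share of uridine at the plus-strand positions was highest at a shift of 0 nt in both replicates, out of shifts of up to 2000 nt either way, and stood 9.44 and 11.6 SDs above the shifts more than 10 nt away. The highest covered position was 16159 in replicate 1 and 16241 in replicate 2. Mitochondrial sequence came from the 37 reference transcripts, 15365 bases without conflict.

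Overlap was the share of positions of one replicate found at the same nucleotide and strand in the other, beside 100 circular shifts of replicate 2 along each chromosome by 1 to 10 kb and 100 by 1 to 50 Mb. Agreement was the Pearson and Spearman correlation of log2(cDNAs + 1) per 10 kb window and strand, with standard errors from leaving out each chromosome. Windows with at least 50 cDNAs were tested for a difference between replicates with a two-sided exact binomial test against the library totals at a 5% false discovery rate (Benjamini-Hochberg), an analysis added after the tracks were seen. Motifs were searched within 25 nt of mitochondrial positions against positions 100 nt away on either side and, as an addition, against 100 random circular shifts. Nuclear copies were 30 nt sequences of the mitochondrial genome found without mismatch in any other reference transcript, on either strand, and each position was judged by the 30 nt that follow it along the strand. Outside the empty stretch, cDNAs at copied positions were compared with the number that the density of the other positions of the same genes would give.

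The rule for named items was fixed before the data were examined: without an annotation of the build used, the 10 windows of 10 kb with the highest value in the lower of the 2 replicates, and mitochondrial genes. Windows that differed between the replicates and positions inside windows were chosen after their values were seen.

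The procedures were tested on simulated data. With 3000 shared positions planted in clustered sets the overlap exceeded the 1 to 10 kb shifts by 3143, and with none planted by 140. Positions were drawn evenly around each cluster centre, so this test does not cover dense stretches shorter than the shifts. With 200 of 13920 windows changed between the replicates, 98% of those changed 4-fold and 29% of those changed 2-fold were called, with 5 unchanged windows called. A motif at 54.1% of positions was found at 52.7%. Alternatives covered the overlap rule, strand, merging of positions, thinning of replicate 2, window size, pseudocount, weighting, background shift and leaving out each replicate. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.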

Results

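The series held 8 mouse samples in 3 groups. Hearts of adult mice that lacked SRSF3 in cardiomyocytes after tamoxifen (3 hearts) and hearts of control mice (3 hearts) were profiled by RNA sequencing, and SRSF3-bound RNA was mapped by iCLIP in neonatal cardiomyocytes (2 replicates). SRSF3 is a small member of the SR protein family, which binds RNA and acts in splicing and mRNA export. iCLIP crosslinks a protein to RNA in living cells with UV light and reads the position where the reverse transcriptase stopped, next to the crosslinked nucleotide. The bound protein here was SRSF3 fused to green fluorescent protein, made from a transfected modified mRNA. The 6 heart samples are not analysed here, so the knockout was not compared with the control, and all values below come from the iCLIP tracks.

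Replicate 1 listed 769652 positions with 815414 cDNAs and replicate 2 listed 2093525 positions with 2253688 cDNAs, so replicate 2 was 2.76 times as deep. Most positions held a single cDNA, 96.9% in replicate 1 and 95.9% in replicate 2. The highest count at a position was 177 cDNAs in replicate 1 and 247 in replicate 2. A count of 0 over a window allows up to 3.68 cDNAs per 1000000 cDNAs of the library (CPM) in replicate 1 and 1.33 CPM in replicate 2. The labels do not say whether the replicates came from separate cultures, so a p-value between them compares these 2 libraries, covers counting error only, and leaves open that a difference is technical. There was no control immunoprecipitation to give a background. RNA abundance in these cells is not given by the tracks either. cDNA counts also follow abundance, so a high value here need not mean a preference of SRSF3.

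Where the most SRSF3-GFP cDNAs lay was asked first, with 10 kb windows on each strand of the mm9 genome and no correction for RNA abundance. The strongest window was on chromosome 19 from 5790001 to 5800000 on the minus strand, with 12479 ± 748 CPM (SD, n = 2). Its signal continued into the next window, 5800001 to 5810000, with 5978 ± 549 CPM (SD, n = 2). The middle 95% of cDNAs of these windows ran from 5796106 to 5799912 and from 5800102 to 5802582, and 95.3% and 91.2% of the replicate 1 positions there were also found in replicate 2. Replicate 2 listed 3669 and 2271 positions in these windows, against 3807 and 2481 nt in those spans. Shares near these would thus arise from its dense coverage alone. Chromosome 17 from 39980001 to 39990000 on the plus strand came next, with 7560 ± 1274 CPM (SD, n = 2), and the first 10000 nt of the mitochondrial plus strand held 6370 ± 884 (SD, n = 2).

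Chromosome 14 had 3 neighbouring windows among the 10 strongest, all on the minus strand. They started at 55560001, 55570001 and 55580001 and held 1593 ± 125, 2630 ± 148 and 1486 ± 7.17 CPM (SD, n = 2). In each of the 3 windows the cDNAs were spread over 1902 to 3673 positions, and no position in either replicate held more than 1.65% of a window's cDNAs. The opposite case was chromosome 9 from 78020001 to 78030000 on the minus strand. Its 1797 ± 524 CPM (SD, n = 2) lay on 127 positions, and 95% of them fell within 102 nt, from 78023148 to 78023249. The last nuclear window was on chromosome 19 from 5840001 to 5850000, minus strand, with 1281 ± 19.7 CPM (SD, n = 2). The second mitochondrial window held 1208 ± 8.85 (SD, n = 2). Together the 10 windows held 4.54% of the cDNAs of replicate 1 and 3.93% of those of replicate 2.

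**Figure D1:**
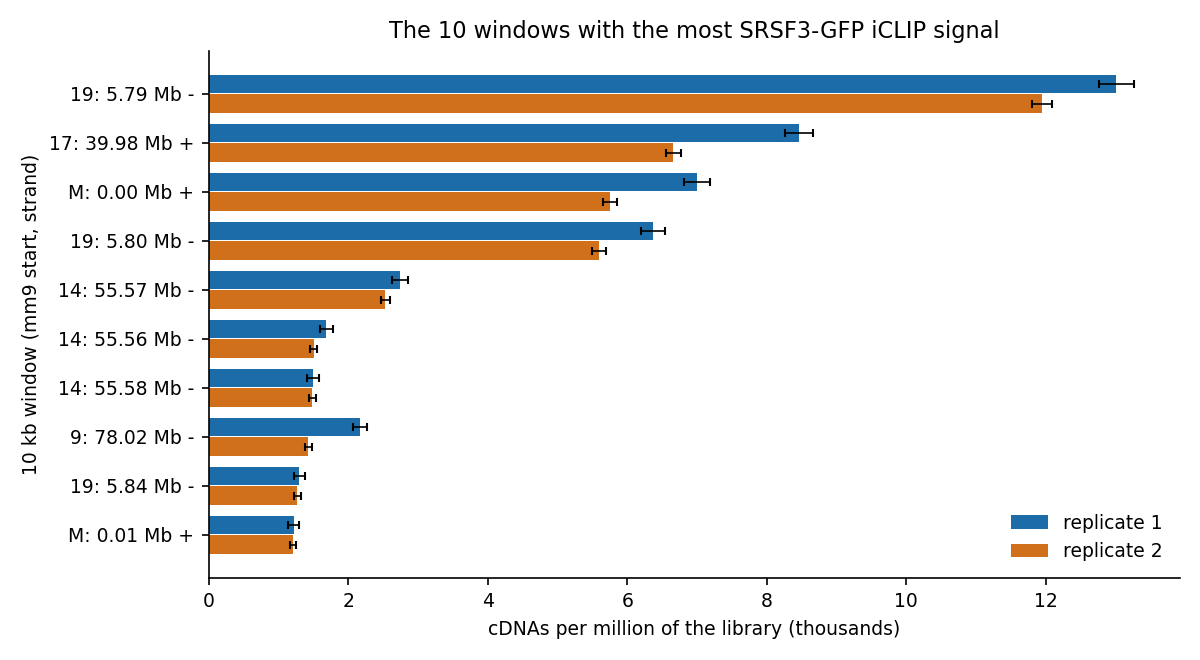
Horizontal bars give cDNAs per 1000000 of the library, in units of 1000, in the 10 strongest 10 kb windows, named by mm9 chromosome, start and strand, for replicate 1 (blue) and replicate 2 (orange), with exact 95% Poisson intervals as error bars. The windows range from 12479 to 1208 CPM as a mean of the replicates.

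For most windows no difference between the replicates was detectable, and the few that differed were mainly higher in replicate 1. Of 13920 windows with at least 50 cDNAs, 13 differed at a 5% false discovery rate (exact binomial test against the library totals, Benjamini-Hochberg adjustment), 11 of them higher in replicate 1. Before adjustment 775 windows, 5.57%, had a p under 0.05. The chromosome 17 window was higher in replicate 1 by 0.35 on the log2 scale (95% interval 0.30 to 0.39, adjusted p = 5.93e-55, exact binomial test), and the chromosome 9 window by 0.60 (0.52 to 0.69, adjusted p = 1.82e-39, exact binomial test). The chromosome 19 windows starting at 5790001 and 5800001 and the first mitochondrial window were also higher, by 0.12, 0.19 and 0.28. A compact site on chromosome 16, with 95% of its cDNAs between 11144126 and 11144317 on the plus strand, was higher by 1.03 (0.86 to 1.20), and a site of 54 nt on chromosome 12, from 55797767 to 55797820, by 0.69 (0.53 to 0.85). Only chromosome 7 from 118210001, minus strand, and chromosome 12 from 73080001, plus strand, were higher in replicate 2, with log2 ratios of replicate 1 to replicate 2 of -0.60 and -1.96. Without the 13 windows the chi-square per degree of freedom was 1.10 (p = 5.13e-15), so the libraries differed by slightly more than counting error and were kept as 2 samples.

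**Figure D2:**
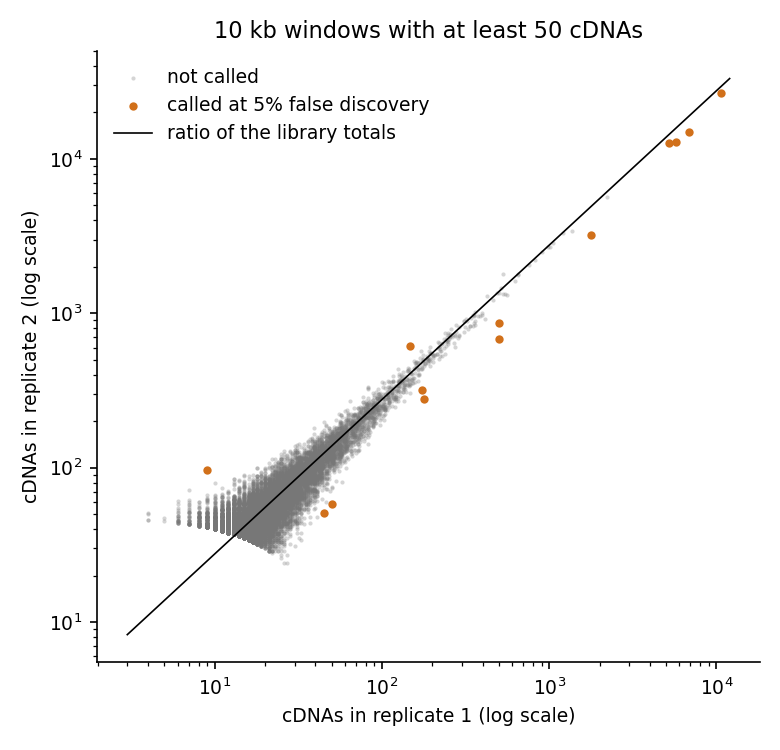
Each point is a 10 kb window on 1 strand with at least 50 cDNAs, placed by its cDNAs in replicate 1 and in replicate 2 on log axes; the line is the ratio of the library totals, 2.76. The 13 windows called different are in orange, and 11 of them lie below the line, on the side of replicate 1.

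Among the autosomes and chromosome X, chromosomes 19 and 11 were the most densely covered and chromosome X the least. Relative to all autosomes together, chromosome 19 held 1.61 ± 0.12 times as many positions per megabase (SD, n = 2), chromosome 11 held 1.41 ± 0.012 times and chromosome 17 held 1.35 ± 0.032 times. Chromosome X held 0.389 ± 0.0068 times the autosomal density, and chromosome 12, the lowest autosome, 0.707 ± 0.0099 times (SD, n = 2). Without the 10 named windows chromosome 19 held 1.40 ± 0.024 times and chromosome 11 held 1.43 ± 0.0056 times, so the rank of chromosome 19 rested on its 3 named windows. Lengths were taken as the highest covered position. The most covered 1% of windows held 17.0% of the positions of replicate 1 and 20.2% of those of replicate 2. Signal in most windows lay on a single strand. Of windows with at least 50 cDNAs over both strands, 94.1% in replicate 1 (1358 of 1443, Wilson 95% interval 92.8% to 95.2%) and 89.2% in replicate 2 (8295 of 9302, 88.5% to 89.8%) had at least 90% of their cDNAs on a single strand.

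**Figure D3:**
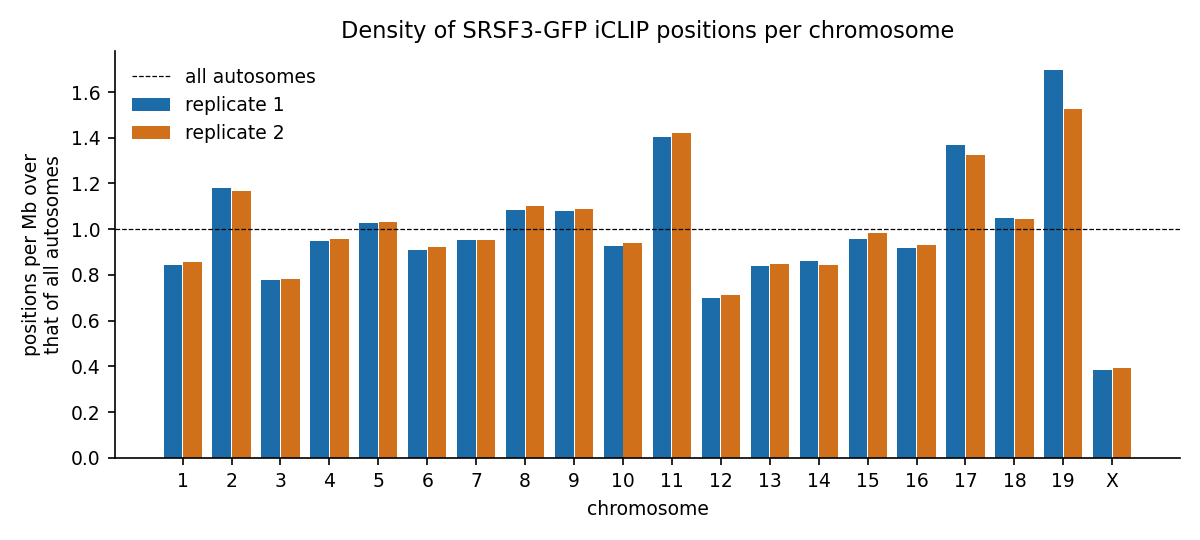
Bars give SRSF3-GFP iCLIP positions per megabase of each chromosome over that of all autosomes, for replicate 1 (blue) and replicate 2 (orange); the dashed line is the autosomal value of 1. Chromosome 19 stands highest at 1.70 and 1.53, and chromosome X lowest at 0.384 and 0.393.

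How far single binding positions recurred between replicates depended on how often they were seen. Of the replicate 1 positions with 1 cDNA, 3.94% were also listed in replicate 2 (Wilson 95% interval 3.90% to 3.99%), against 24.2% of those with 2 cDNAs and 86.2% of those with 3 to 5. All 544 positions with more than 10 cDNAs recurred. No shifts are given per class, so recurrence by chance in stretches that replicate 2 covered densely is not taken off these shares. Over all positions, 38674 were shared on the same strand, 5.02% of replicate 1 (4.98% to 5.07%) and 1.85% of replicate 2 (1.83% to 1.87%). On the mitochondrial genome 71.8% of the replicate 1 positions were shared, but replicate 2 listed 4768 positions there, and such dense coverage alone raises this share.

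Sharing exceeded chance placement at the scale of the shifts. Circular shifts of replicate 2 by 1 to 10 kb gave 8748 ± 2323 shared positions (SD over 100 shifts), so the observed number was 4.42 times as high, and shifts of over 1 Mb gave 1065 ± 269, a ratio of 36.3. Outside the mitochondrial genome replicate 2 positions peaked on the replicate 1 position itself, at 4.51 times the mean of the shorter shifts, and fell to 2.57 at 10 nt and 2.04 at 100 nt downstream. At the same coordinate on the opposite strand, replicate 2 had a position at 228 of the replicate 1 positions, against 36623 on the same strand. Without the mitochondrial genome and the unplaced sequences the ratio to the long shifts was 115. Counting positions within 10 nt as shared gave 23.6% of replicate 1, against 11.6% in the shifts of 1 to 10 kb, a ratio of 2.04.

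**Figure D4:**
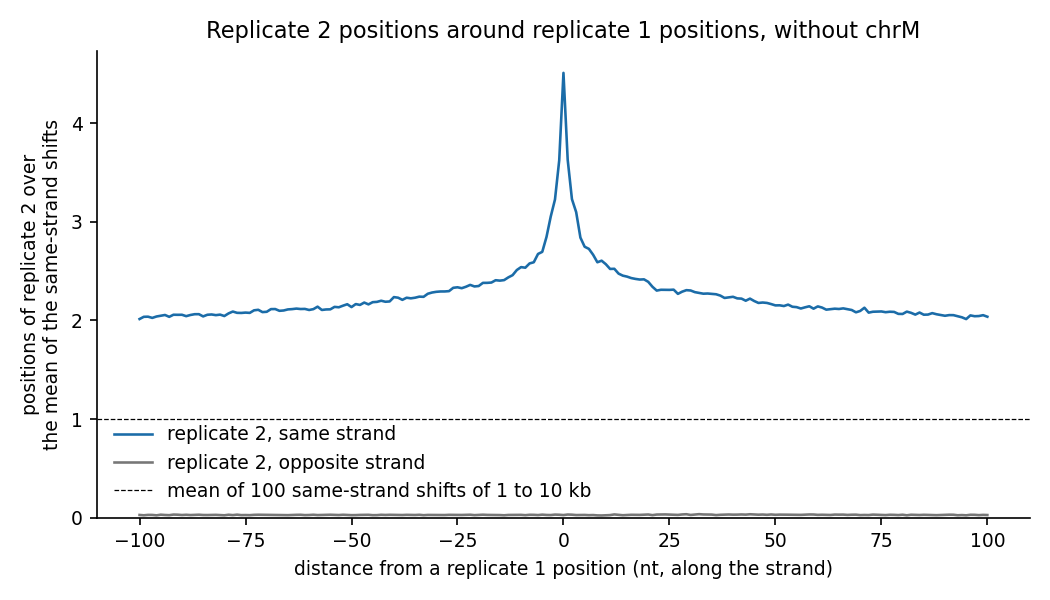
The number of replicate 2 positions at each distance from a replicate 1 position, along the strand in nt, is drawn over the mean of 100 same-strand shifts of 1 to 10 kb (dashed line at 1), for the same strand (blue) and the opposite strand (grey), without the mitochondrial genome. The same-strand curve peaks at 4.51 at distance 0 and the opposite-strand curve stays near 0.

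cDNA counts per window were correlated between the replicates slightly more closely than in random splits of the pooled cDNAs. Across the 237938 windows with a position in either replicate, log2(cDNAs + 1) had a Pearson r of 0.832 and a Spearman rho of 0.595 (jackknife SE over chromosomes 0.0045 and 0.013). When the pooled cDNAs of each window were split at random in the ratio of the library totals, 20 draws gave a mean r of 0.826 and a mean rho of 0.578, with highest values of 0.826 and 0.580. Both observed values lay above all 20 draws, and the cause was not tested. These correlations are across windows, which are not independent replicates. They depended on window size, with r = 0.443 for 1 kb windows and 0.920 for 100 kb windows, and on the pseudocount, with r = 0.560 at 0.1.

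On the mitochondrial genome SRSF3-GFP cDNAs lay mainly on the 2 ribosomal RNAs. The mitochondrial genome took 6897 cDNAs of replicate 1, 0.846% of the library (Wilson 95% interval 0.826% to 0.866%), and 16097 of replicate 2, 0.714% (0.703% to 0.725%). The plus strand, which carries both ribosomal RNAs and 12 of the 13 mRNAs, held 97.1% and 97.3% of them. mt-Rnr2, the large ribosomal RNA (M, 1094 to 2675, plus strand), had 2170 ± 382 CPM per kb (SD, n = 2), and mt-Rnr1, the small ribosomal RNA (70 to 1024, plus strand), had 1925 ± 276. The strongest position in mt-Rnr2, at 1672, held 132 and 247 cDNAs. The ribosomal RNAs made up 69.6% of the mitochondrial cDNAs of replicate 1 and 65.2% of those of replicate 2. These shares are taken with a stretch of mRNAs nearly empty, as described below.

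The mitochondrial mRNAs were covered several times less densely than the ribosomal RNAs. mt-Nd2, which encodes a subunit of respiratory complex I, had 405 ± 13.9 CPM per kb, mt-Nd5, also of complex I, had 319 ± 1.32, and mt-Nd1, another subunit of that complex, 271 ± 22.6 (SD, n = 2). mt-Cytb, the cytochrome b of complex III, had 216 ± 14.6 and mt-Nd6, the only mRNA of the minus strand, 134 ± 21.2. Some transfer RNAs stood higher: mt-Tm, mt-Tv and mt-Tf had 709 ± 229, 567 ± 28.2 and 545 ± 96.8 CPM per kb (SD, n = 2), while all 22 transfer RNAs together had 159 in replicate 1 and 127 in replicate 2 and 5 of them had no cDNA. Of those 5, mt-Ts1, mt-Td, mt-Tk and mt-Tr lie in the nearly empty stretch described below. Their length still counts in the joint value.

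No cDNA of either replicate fell on mt-Co2, mt-Atp8, mt-Atp6, mt-Co3 or mt-Nd4l, which lie in the same part of the genome and encode subunits of complexes IV, V and I. At mt-Co2 (684 nt) this allows up to 5.38 CPM per kb in replicate 1 and 1.95 in replicate 2. mt-Co1 and mt-Nd4, at the ends of this stretch, were covered in part only: 192 of the 214 cDNAs of mt-Co1 in replicate 1 and 139 of the 142 of mt-Nd4 lay where no identical 30 nt sequence occurred in a nuclear transcript. Between positions 6387 and 10982 the plus strand held 1 cDNA in replicate 1 and 5 in replicate 2, and 88.5% of the known positions there had such a nuclear copy. The share was 100% for mt-Co2 and 96.0% for mt-Co3 but 21.6% for mt-Atp8.

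Between the replicates, mt-Rnr2 and mt-Rnr1 differed among the 27 mitochondrial genes with any cDNA (exact binomial test, adjusted p = 1.09e-28 and 1.41e-10), both higher in replicate 1, by 0.36 and 0.29 on the log2 scale. Before adjustment 4 genes had a p under 0.05. These p-values cover counting error only. No other mitochondrial gene passed, and mt-Nd5 and mt-Co1 had log2 ratios of -0.01 and -0.01.

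**Figure D5:**
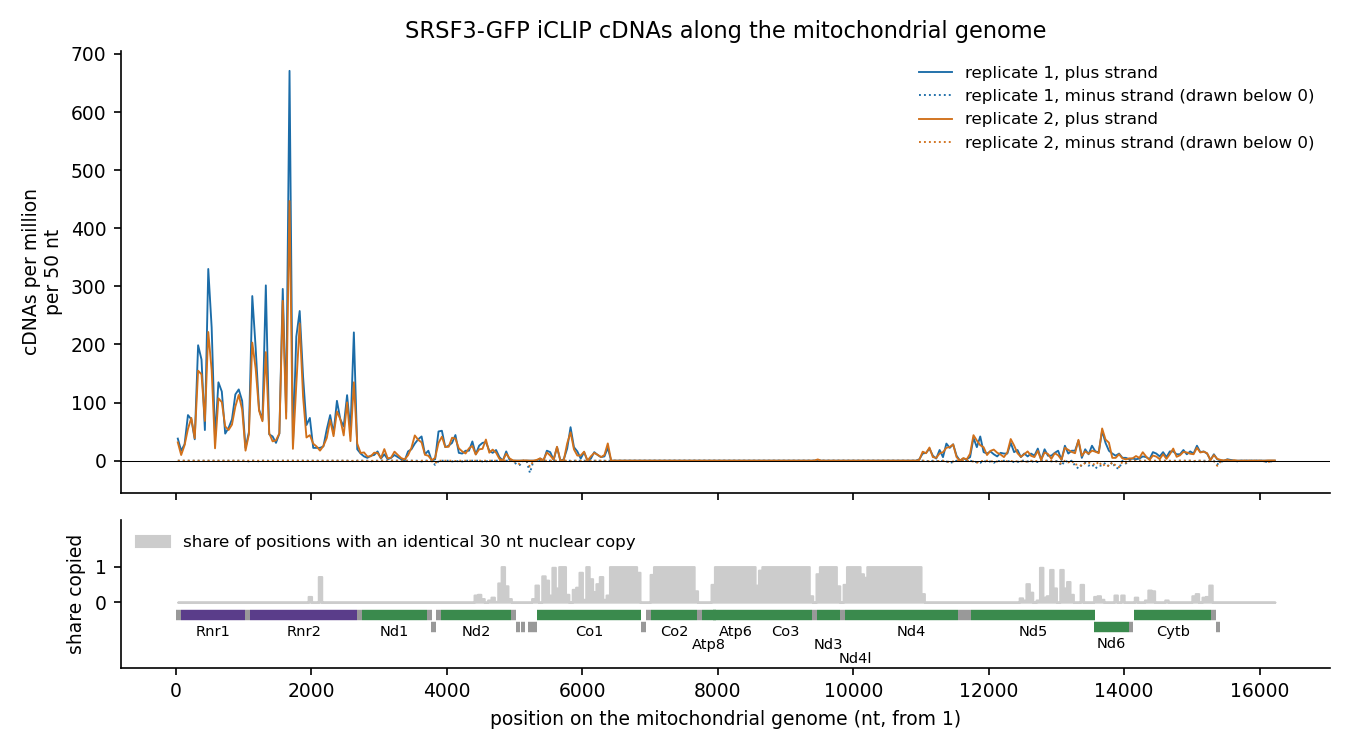
The upper panel shows CPM per 50 nt along the mitochondrial genome for replicate 1 (blue) and replicate 2 (orange), plus strand above 0 and minus strand below 0; the lower panel shows the share of positions with an identical 30 nt sequence in a nuclear transcript (grey) above the genes (ribosomal RNAs purple, mRNAs green, transfer RNAs grey; minus-strand genes lower). The tallest peak lies in mt-Rnr2, and the stretch between 6387 and 10982 is nearly empty in both replicates.

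Sequence around the positions could be examined on the mitochondrial RNAs only. Without a control immunoprecipitation these cDNAs cannot be told from background. A motif found or not found there therefore does not show whether SRSF3 prefers it. Uridine was the base at 35.9% of the plus-strand positions of replicate 1 and 35.0% of those of replicate 2, against means of 27.8% and 27.9% at other shifts of up to 2000 nt. The same peak was used to check the numbering, on which all motif values here depend, so it is not a separate measure of preference. UUUUU, included as a control motif, was found within 25 nt at 5.89% of positions in replicate 1 and 5.83% in replicate 2, which 12 and 10 of 100 random shifts of the positions reached. Within 5 nt, a width chosen after the data were seen, it was found at 1.90% of positions in replicate 1 and 1.76% in replicate 2, above all 100 random shifts, whose highest were 1.44% and 1.38%. This excess is not independent of the same uridine peak and is not a separate measure of preference either. The published SRSF3 motif WCWWC (W is A or U) was found within 25 nt of 50.2% of positions in replicate 1 and 50.3% in replicate 2, and 59 and 53 of the 100 random shifts gave at least as much. CNNC was found within 25 nt of 86.0% and 85.1% of positions, a level that 80 and 97 of the 100 shifts reached, and its share within 5 nt, 31.6% and 32.4%, was reached by 97 and 94 of the 100 shifts. Against positions 100 nt away, ratios within 25 nt were 1.08 and 1.05 for WCWWC and 1.03 and 1.00 for CNNC. For UUUUU they were 1.07 and 0.977.

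GGAGA, a purine motif also included as a control, was found within 25 nt of 5.75% and 5.62% of positions, a level that 3 and 2 of the 100 shifts reached. Its ratio to positions 100 nt away was 1.31 and 1.34 within 25 nt. Within 5 nt that ratio was 0.641 and 0.848, and 52 and 35 of the 100 shifts reached the shares of 0.423% and 0.508% there. Of 952 pentamers ranked by the lower of the replicate ratios, GAGUG came first, with 2.65 and 2.22, on 0.674% and 0.705% of positions and 12 occurrences in the sequence. Neighbouring positions share sequence and are not independent, and these values describe mitochondrial RNA only.

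The merged list held 3846902 positions and 4207555 cDNAs and contained every position of both replicates. Of its positions, 53.4% were in replicate 2 only, 1.01% in both and 26.6% in neither (Wilson 95% interval 26.5% to 26.6%). Its value equalled the sum of the replicates at 98.4% of the replicate positions and was never below it. Its header names 5 libraries, the 2 replicates and 3 more.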

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

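The tests of nuclear copies, of single-cDNA windows, of differing windows higher in replicate 2 or without deep positions and of the other libraries against counting error were chosen only after the result was seen.

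The merged list holds 1022399 positions found in neither replicate, a signal outside the data that the comparisons above use, and its header names 3 further libraries, whose single tracks are not used here. In these other libraries 6083 of 21841 windows with at least 50 cDNAs differed from replicates 1 and 2 together at a 5% false discovery rate (two-sided exact binomial test, Benjamini-Hochberg), 3160 of them higher. An unadjusted p under 0.05 was found in 37.7% of these windows, where counting error alone would give about 5%, and in 5.57% of windows between the replicates.

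The replicates share exact positions. Chance placement at the scale of 1 to 10 kb is argued against by the ratio of 4.42 to shifts of that size, whose highest of 100 was 13915 shared positions. Such shifts leave any shorter dense stretch, and outside the mitochondrial genome positions 100 nt away stood at 2.04 times their mean. Chance within shorter dense stretches is therefore not excluded by them. A few very deep windows are argued against by the ratio of 4.70 without the 10 named ones, though these held 27.4% of the shared positions. Reads carried over within a sequencing run may contribute, and the headers, which give the replicates the same library identifier and the other libraries different ones, do not name the runs, so this stays open. Without those 10 windows, exact positions stood above positions 10 to 20 nt away 2.24 times (jackknife SE 0.056) between the replicates, 2.14 times (SE 0.032) between replicate 1 and the other libraries and 1.997 times (SE 0.015) between replicate 2 and the other libraries. The first thus exceeded the second by 0.0997 (SE 0.065) and the third by 0.247 (SE 0.058). With all windows the first exceeded the second by 0.190 (SE 0.349). The SEs of these differences combine the separate SEs as if the ratios were independent. The ratios share a replicate and the same chromosomes, so the SEs need not measure the spread of the differences and cannot decide this. In windows with a single cDNA of each library, 32.7% of pairs within 5 nt were at the same position for the replicates and 24.0% for replicate 1 and the other libraries (two-sided Fisher's exact p = 0.0299). No biological explanation was tested, since both libraries belong to the same group.

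The mitochondrial plus strand between positions 6387 and 10982 was nearly empty. A candidate explanation is that reads which also match a nuclear copy were left out. Outside this stretch, positions with an identical 30 nt copy in a nuclear transcript held 17.2% (95% interval 13.6% to 21.4%) of the cDNAs that the other positions of the same 6 genes would give in replicate 1 and 19.4% (16.9% to 22.0%) in replicate 2, a loss that is not complete. The longest unbroken row of copied positions outside was 119 nt, against 754 nt wholly inside the stretch. The comparison outside thus rests on shorter copies and cannot say how complete the loss is at long ones. The 508 positions of the stretch without such a copy held 1 and 5 cDNAs, but the stretch was chosen because it was empty and copies outside annotated transcripts were not searched, so this explanation stays open. No biological explanation was tested, and whether SRSF3 binds mt-Co2, mt-Atp8, mt-Atp6, mt-Co3 and mt-Nd4l cannot be read from these tracks.

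Of the 13 windows that differ between the replicates, 8 were higher in replicate 1 and had a position above 20 cDNAs. Random barcodes that ran out in replicate 2 are a candidate cause there. At positions of these windows with at most 1 cDNA in the other libraries, the ratio of replicate 2 to replicate 1 was 2.56 (95% interval 2.49 to 2.64), below the 2.76 of the libraries. These positions held 2.54 cDNAs of replicate 2 on average and at most 29, while another position of these windows reached 247. At 2 to 5, 6 to 20 and more than 20 cDNAs in the other libraries the ratio was 2.54, 2.27 and 1.60. In all other windows it was 2.79 at positions with at most 1 cDNA, which averaged 1.04 cDNAs of replicate 2, and 2.51 at 2 to 5, which averaged 2.91. It was 2.20 and 2.44 (95% interval 2.12 to 2.81) above that. Up to 20 cDNAs in the other libraries, positions of like depth in replicate 2 thus gave a similar ratio. Above 20 the 8 windows stood lower, at 1.60 (95% interval 1.54 to 1.66) against 2.44. Their positions there were also deeper, with 58.6 cDNAs of replicate 2 on average against 30.1. The 8 windows were chosen for a low ratio. The low positions therefore cannot decide this, and a contribution at the deepest positions may remain. A random barcode limit of replicate 2 cannot account for the 2 differing windows that are higher in replicate 2, nor for the 3 others without a deep position, where replicate 2 had at most 15 cDNAs at a position. No biological explanation was tested, since both libraries belong to the same group.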

How the results depend on the processing

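The alternatives with at least 2 cDNAs per position, without the 10 named windows, for windows of at least 50 cDNAs, with 5 nt flanks, with motifs weighted by cDNAs and for the window test, positions in place of cDNAs for the named windows and thinning and leaving out the named windows for the distribution were chosen after seeing the data. Of 148 values under an alternative for 35 results, 87 stayed within the spread of their result (or 1.5 times a count) and 61 moved beyond it, 10 of these the named windows given as positions. That spread was between the replicates only where each replicate has its own value. Overlaps and correlations take both replicates for a single value and were judged by another spread, such as the SD over shifts for the ratios. Leaving out a replicate returns the other replicate's value, which lies within the spread by construction, and an overlap of at least 50%, identical ends or the median score change nothing for positions of 1 nt with a median of 1 cDNA. No paired analysis was possible because the knockout and control hearts are not analysed here and the iCLIP has a single group. Also not run were the top 10% of positions by score, since the 90th percentile is 1 cDNA, and the gene region and gene list alternatives, which need an mm9 annotation. Depth limits what single positions show, as 96.9% of those of replicate 1 rest on 1 cDNA.

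Shared positions were 5.02% of replicate 1, 1.85% of replicate 2, 4.42 times the 1 to 10 kb shifts and 36.3 times the shifts over 1 Mb. Within 10 nt these became 23.6%, 11.6%, 2.04 and 24.0, and for positions merged within 15 nt 6.22%, 2.24%, 2.75 and 56.7. With at least 2 cDNAs per position the shares were 29.9% and 8.32% and the first ratio 8.36. Thinning replicate 2 gave 2.60% and 2.56%, by the smaller depth. Without the mitochondrial genome and unplaced sequences the shares were 4.78% and 1.75% and the long-shift ratio 115, and without the 10 named windows 3.72%, 1.36% and 89.4. Ignoring the strand gave a long-shift ratio of 26.8. The ratios stayed above 1 under each of these.

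Pearson r, 0.832, was 0.560 with a pseudocount of 0.1, 0.889 for windows covered in both replicates, 0.443 for 1 kb and 0.920 for 100 kb windows, and 0.895 for windows of at least 50 cDNAs. Spearman rho, 0.595, was 0.871, 0.256, 0.747 and 0.776 under the last 4. Weighting positions by cDNAs gave 21.8% in the top 1% of windows, 2.17 for chromosome 19, 0.376 for chromosome X and 0.780% for the mitochondrial genome, and 1 kb windows gave 12.7% in the top 1%. Without the 10 named windows chromosome 19 stood at 1.40, below the 1.43 of chromosome 11. The number of differing windows, 13, was 20 with 1 kb windows and 23 for positions in place of cDNAs.

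Mean motif ratios to positions 100 nt away were 1.07 for WCWWC, 1.02 for CNNC, 1.33 for GGAGA and 1.02 for UUUUU. A shift of 500 nt gave 1.13 for WCWWC, 1.17 for GGAGA and 1.12 for UUUUU. Flanks of 5 nt gave 1.11 for WCWWC, 0.998 for CNNC, 0.745 for GGAGA and 1.72 for UUUUU. Positions with at least 2 cDNAs gave 1.13 for WCWWC, 1.04 for CNNC and 1.501 for GGAGA. Weighting by cDNAs gave 1.22 for WCWWC, 1.05 for CNNC, 1.69 for GGAGA and 0.779 for UUUUU. GGAGA, CNNC and UUUUU thus changed sides of 1 between settings, and except for thinning the cause was not tested.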

Other observations

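The tests and regions in this part were chosen after the values were seen. SRSF3-GFP signal formed long runs on a single strand, and the runs counted here include the 10 named windows. Windows with at least 100 CPM in both replicates numbered 453 and fell into 223 runs, 38 of them of 3 or more windows. The longest covered 280 kb of chromosome 2, from 76540001 to 76820000 on the minus strand. It held 12814 CPM in replicate 1 and 12159 in replicate 2, about as much as the strongest single window, with 99.9% and 99.8% of the cDNAs there on that strand. The next were 170 kb of chromosome 6 from 118840001, minus strand (2303 and 2302 CPM), 150 kb of chromosome 17 from 81900001, minus strand (4124 and 4101), and 110 kb of chromosome 13 from 12090001, minus strand (2253 and 2240). On the plus strand the longest were 100 kb of chromosome 8 from 46820001 (2015 and 2100) and 100 kb of chromosome 19 from 53750001 (2147 and 2093). In these 6 runs the other libraries of the merged list had lower values, with log2 ratios to the replicates from -1.05 to -0.58.

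Chromosome 14 carried signal on both strands side by side. The minus strand from 55550001 to 55590000 held 6090 CPM in replicate 1 and 5676 in replicate 2, and the plus strand from 55580001 to 55630000 held 2166 and 2057, with 57.9% and 56.6% of the cDNAs of that second stretch on the plus strand. The stretches overlap from 55580001 to 55590000. That window held 1216 and 3338 of the 1284 and 3550 minus-strand cDNAs of the second stretch, so both strands were mixed mainly there.

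The plus strand opposite mt-Nd6, a gene of the minus strand, was covered at 275 cDNAs per kb in replicate 1 and 782 in replicate 2 between 13566 and 14070. That was close to mt-Nd5 just upstream, with 259 and 721, and above mt-Nd6 itself, with 121 and 268. The minus strand opposite mt-Nd5 held 40.3 and 82.9 cDNAs per kb.

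The libraries of the merged list beyond the replicates also differed from them in windows named above. The 3 chromosome 14 windows starting at 55560001, 55570001 and 55580001 on the minus strand were lower there than in the replicates, by log2 ratios of -1.54, -1.41 and -1.36, and the chromosome 17 window starting at 39980001 was higher, by 0.64. In 13 windows they had at least 50 cDNAs and the replicates none, led by chromosome 3 from 127240001 to 127250000 on the plus strand with 236 cDNAs on 179 positions.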
